A study of Homo sapiens with 6 samples.

How the data were processed

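Gene expression was measured by RNA sequencing in primary human myotubes from 3 lean and 3 obese donors, 1 sample per donor. Per the labels' protocols, myoblasts were switched at about 80% confluence from serum-rich to low-serum medium to form myotubes, which were washed and frozen, and total RNA was extracted on columns. Per the series' design text, RNA integrity numbers exceeded 8, libraries were poly-A selected, and an Illumina HiSeq2000 gave at least 20 M paired-end reads of 2 x 101 bases per sample. TopHat, Cufflinks and the build GRCh37 are also named in the submitters' processing notes, without versions. Per the series' design text, the reads were aligned with TopHat, RefSeq served as the gene model and the authors tested genes with Cufflinks. The authors deposited 1 table of RPKM values, with 1 column per sample. The tool that made the RPKM values and any scaling between samples are not given in the sources used here. The authors' own test needs the reads and was not repeated.

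The table held 21563 rows, each with a gene symbol and coordinates. Because the samples come from people, 123 rows (genes of the Y chromosome, XIST and TSIX) were removed before anything was computed. Rows that shared a symbol were summed (24 symbols), giving 21413 symbols. Of these 26 had been turned into dates by spreadsheet software, 14 of which were tested, and these are not named. Genes with a mean of at least 1 RPKM over the 6 samples were kept (8164 genes, 38.1%). The poly-A libraries are not stated to keep strand, so reads of a gene and of an antisense neighbour cannot be told apart, and how reads shared by paralogs were assigned is not known. Genes such as those of ribosomal proteins or actins are uncertain for that reason.

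Groups came from the donor phenotype in the labels. The replicate numbers count donors within a group. The test, the gene lists and the rule for naming genes were fixed before the data were examined, as were 20 of the 24 alternatives. Limma was run on log2(RPKM + 1) with a group term (empirical Bayes with a mean-variance trend, 2-sided), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. RPKM are not counts, so no count model was used. LPCAT3 and the mean scores of the sarcomere and excitation-contraction lists were also given a 2-sided exact permutation test, which cannot go below 0.1 with 3 against 3, and each gave 0.1.

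Of the lists, 22 hold genes of pathways and 6 hold markers of cell types (fibroblast, adipocyte, endothelial, pericyte and smooth muscle, leukocyte and macrophage, neural). The 23 lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the 23 lists. Members were also counted when adjusted over the list alone. Genes to be named were, in each direction, the 12 with the largest fold change among those past the threshold with non-overlapping groups, filled up with the genes of smallest unadjusted p and non-overlapping groups. As 0 genes passed, all 12 in each direction are such genes. Added to these were, for each list, the 3 tested members with the smallest unadjusted p, and LPCAT3. Identifiers that name no gene, and genes whose level is known to follow a common germline deletion or splice variant, were never named. Not every gene this rule takes is named in the text. DCN, an abundant fibroblast transcript, and ALDOA, which went against the other genes named from its list, were added after their values were seen.

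Depth was read from the table itself. In genes with a single annotated transcript, 1 read is worth a fixed RPKM set by gene length and depth, and the most frequent such step gave 20.9 to 25.6 M per library. Between 48.3% and 55.6% of the low values (0.6 to 4.4 reads) of these genes lay within 2% of a whole number of reads, so the reads themselves were not recovered. At this depth 1 read in a gene of median length is worth far less than the minimum of 1 RPKM. The spread within groups, of donors and libraries together, limits the precision more than counting error (median residual SD 0.44 on the log2 scale). Data were simulated for this comparison over 8164 genes in 5 simulations, with the spread within groups of the real libraries. Of genes changed by 1 on the log2 scale 15.2% were recovered, with 81.2% of those changed by 2, 97.2% at 3 and 97.6% at 4. A list shifted by 1 was recovered in all 5 simulations. Each simulated gene varied independently and no simulated library stood apart, unlike in the real data. In each simulation 50 genes were changed at each size, beside the shifted list. Adjustment over all genes is more lenient when many genes change strongly, whereas the smallest adjusted p of the real comparison in limma was 0.707. The simulations called 0 other lists, whereas splits of the real libraries other than the donor groups called 3 to 7. The simulated shares can therefore overstate what the real comparison recovers.

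Exonic length and GC content came from GENCODE release 44 mapped to GRCh37. Of 21514 symbols, 17980 matched by current symbol and 2415 through older RefSeq symbols, and 8009 of the tested genes (98.1%) and 41 of 41 sarcomere genes had both. The alternatives planned were pseudocounts of 0.1 and 0.5, no filter and a minimum mean of 5 RPKM, rescaling to equal sums, median-of-ratios scaling, quantile normalization, limma without the trend and with robust estimation, limma's arrayWeights, the highest row per symbol, a replicate block, leaving out each library in turn, and the 2 further list tests. Chosen after seeing the data were the genes with known length and GC alone, removal of a spline trend on log length and GC from each library, that removal with lean replicate 1 left out, and leaving out lean replicate 1 and obese replicate 3, the libraries farthest from the others. Software was R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.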

Results

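RNA was sequenced from primary human myotubes, the multinucleated muscle fibres formed in culture when muscle precursor cells are moved to low-serum medium. The cells came from 3 lean and 3 obese donors, with 1 library per donor, so each group had n = 3. The spread within a group held differences between donors and between libraries, which cannot be told apart. The values are RPKM (reads per kilobase of gene model, scaled to the mapped reads of the library) for 21413 gene symbols, of which 8164 had a mean of at least 1 RPKM and were tested. Depth, estimated from the steps that single reads leave in the lowest values, was 20.9, 25.6 and 21.1 M reads for lean replicates 1 to 3 and 24.6, 22.3 and 22.2 M reads for obese replicates 1 to 3. The design poses 1 question, which transcripts differ between myotubes of lean and obese donors. LPCAT3, an enzyme that acylates lysophosphatidylcholine, was singled out in advance and examined whatever its rank. It was chosen because the laboratory that deposited the data studies lysophospholipid acylation in muscle, so the choice may not be independent of these data. All log2 fold changes are obese minus lean on the log2(RPKM + 1) scale, which understates changes of weakly expressed genes, and errors after ± are SD over n = 3 unless an SE is named. The median log2 fold change over all tested genes was 0.18, and it was -0.02 after median-of-ratios scaling or quantile normalization and 0.08 after rescaling to equal sums. List medians are therefore given relative to that of all genes.

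Genes of the contractile apparatus were expressed at higher levels in myotubes of obese donors. Of 41 tested genes of the sarcomere and myotube maturation list, 41 had a positive log2 fold change and 41 lay above the median of all genes, with a list median of 0.88 relative to all genes. TNNC2, fast skeletal troponin C, measured 294 ± 133 RPKM in lean and 1090 ± 342 RPKM in obese myotubes. ACTN2, the alpha-actinin of the Z-disc, measured 13.2 ± 3.46 and 36.3 ± 5.42 RPKM, and TPM1, a tropomyosin of the thin filament, 187 ± 24.5 and 473 ± 114 RPKM. In TNNT3, fast skeletal troponin T, the means were 50.4 ± 16.9 and 158 ± 59 RPKM, and in MYOZ1, a Z-disc protein that binds calcineurin, 0.524 ± 0.213 and 1.74 ± 0.0317 RPKM. The list differed from the other genes by limma's camera test with a preset inter-gene correlation of 0.01 (adjusted p = 2.93e-38 over 23 lists). It also passed with an estimated correlation (adjusted p = 0.0469) and in fry, which asks whether the genes move one way without comparing them with other genes (adjusted p = 0.0331). In 28 of the 41 genes the 3 obese values all lay above the 3 lean values, or 68.3% where chance gives 10%, counting both directions. Of the 41 genes 26 had an unadjusted limma p under 0.05 and 19 passed when adjusted over the list alone, whereas 0 passed over all genes tested. That count of 19 was 0 without lean replicate 3, 0 without obese replicate 2, 6 without obese replicate 3, and 0 after each of 3 other scalings of the libraries.

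The excitation-contraction coupling and calcium handling list was also higher in obese myotubes. Its 22 tested members all had positive log2 fold changes before rounding, 21 lay above the median of all genes, and the list median was 0.68 relative to it. SLN, which encodes sarcolipin, the small regulator of the sarcoplasmic reticulum calcium pump, had the smallest p of any gene. It lies on chromosome 11 at 107578109 to 107582787 (GRCh37) and measured 190 ± 18.7 RPKM in lean and 783 ± 84 RPKM in obese myotubes (log2 fold change 2.04, SE 0.30), higher in each of the 3 obese libraries than in any lean one, and did not pass in limma (adjusted p = 0.707). TRDN, the junctional protein triadin, measured 2.46 ± 0.535 and 8.36 ± 1.02 RPKM, and SYPL2, a protein of the triad membrane, 0.74 ± 0.275 and 2.26 ± 0.301 RPKM. The camera test gave an adjusted p of 5.37e-19, with 0.0469 under an estimated correlation and 0.0331 in fry. Of the 22 genes, 0 passed over all genes tested and 6 passed in limma when adjusted over the list alone. The latter count was 1 without lean replicate 3, 1 without obese replicate 1 and 3 without obese replicate 2.

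**Figure D1:**
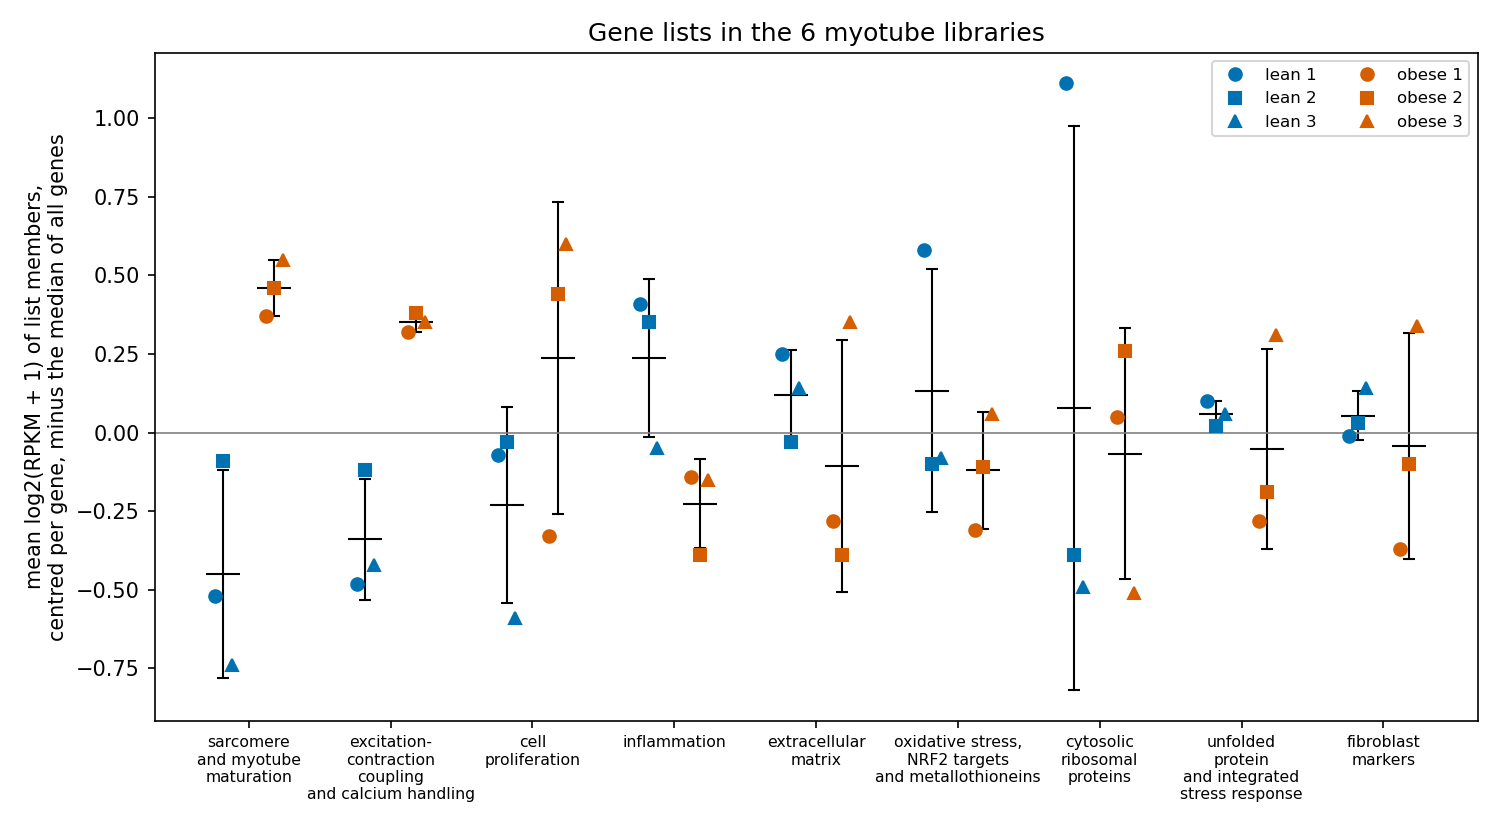
Mean log2(RPKM + 1) of the members of 9 gene lists in each of the 6 libraries, centred per gene and given relative to the median of all genes in that library. Blue marks are lean and orange marks obese libraries, with replicate numbers by shape, and bars are group means with SD (n = 3). For sarcomere genes the 3 obese libraries lie at 0.37, 0.46 and 0.55 and the 3 lean libraries at -0.52, -0.09 and -0.74, whereas for proliferation genes obese replicate 1, at -0.33, lies below 2 of the lean libraries.

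Among the genes of smallest p with non-overlapping groups, 5 named here were higher in obese myotubes. TMOD4, the tropomodulin of skeletal muscle, measured 0.262 ± 0.0795 RPKM in lean and 2.16 ± 0.886 RPKM in obese myotubes. APOBEC2, a muscle member of the cytidine deaminase family, measured 19.3 ± 12.6 and 85.2 ± 22.8 RPKM, MYOT, the Z-disc protein myotilin, 9.46 ± 7.04 and 36.8 ± 10.2 RPKM, and C1orf105 4.34 ± 3.15 and 17.6 ± 5.14 RPKM. FITM1, which takes part in lipid droplet formation in muscle, measured 1.65 ± 0.473 and 6.60 ± 1.79 RPKM. Their log2 fold changes were 1.28 for TMOD4, 2.22 for APOBEC2, 2.02 for MYOT, 1.92 for C1orf105 and 1.51 for FITM1. All 5 had non-overlapping groups and none passed in limma after adjustment. In the other direction, DKK1, a secreted Wnt antagonist, measured 6.27 ± 1.92 RPKM in lean and 2.23 ± 1.03 RPKM in obese myotubes (log2 fold change -1.18). IGFBP3, a binding protein of insulin-like growth factors, measured 61.1 ± 37.6 and 22.1 ± 6.35 RPKM (-1.30 on the log2 scale, -0.84 without lean replicate 1), and CCND1, cyclin D1, 1.63 ± 0.611 and 0.675 ± 0.286 RPKM (-0.64). SERPINE2, a serine protease inhibitor, had a log2 fold change of -1.16 (-0.71 without lean replicate 1), the non-coding transcript NCRNA00162 one of -1.65, KIAA1644 one of -0.89 (-0.56 without lean replicate 3) and C17orf60 one of -0.93 (-0.26 with weighted libraries). KRTAP1-5, a keratin-associated protein gene, had -0.69, GPR137B -0.63 and ID4, an inhibitor of basic helix-loop-helix factors, -0.63. In each of these genes the 3 obese values lay below the 3 lean values, and none passed in limma after adjustment.

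**Figure D2:**
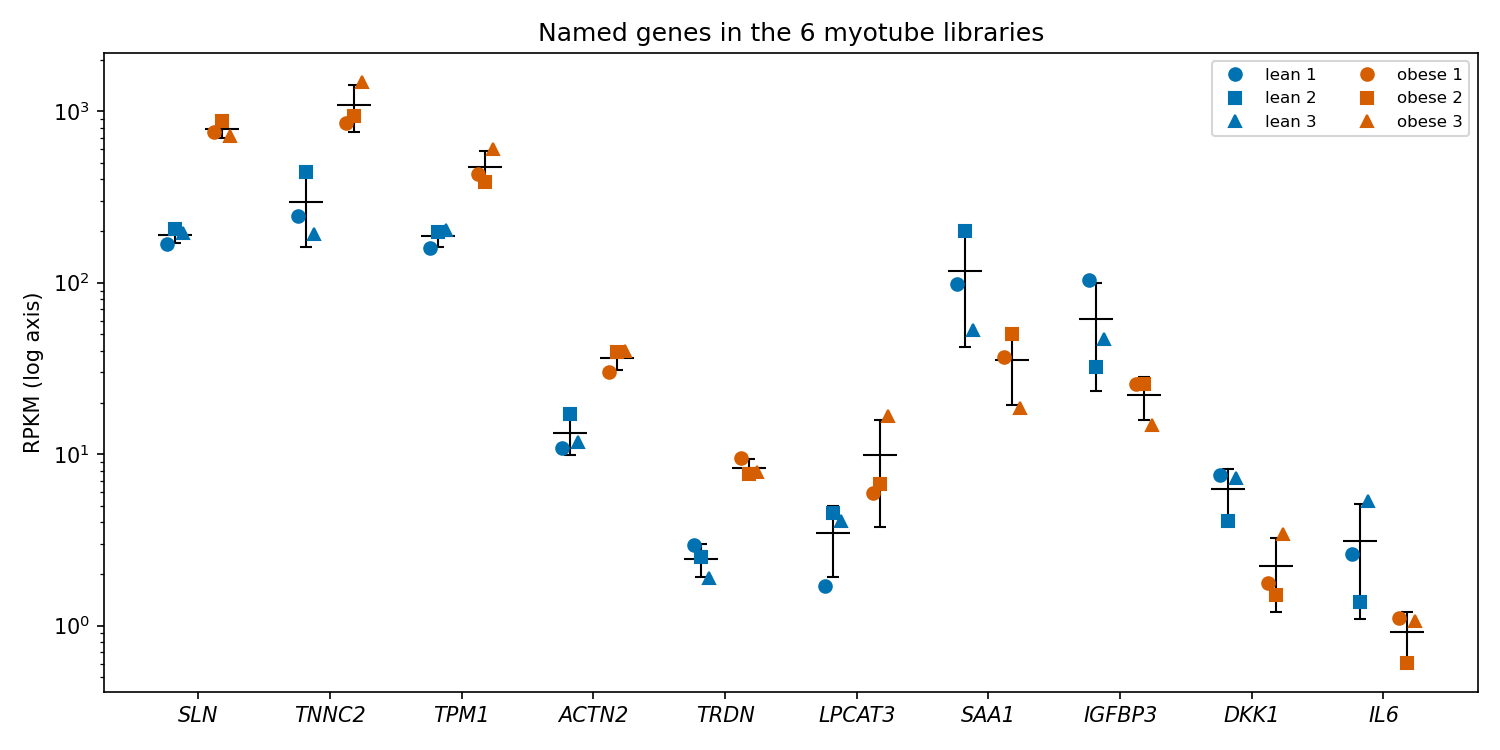
RPKM (log axis) of 10 named genes in each library, with lean libraries in blue and obese in orange, replicate numbers by shape and bars for group means with SD (n = 3). SLN lies between 169 and 206 RPKM in lean and between 713 and 876 RPKM in obese libraries, and LPCAT3 reaches 16.8 RPKM in obese replicate 3 against 5.95 and 6.74 RPKM in the other obese libraries.

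LPCAT3 lies on chromosome 12 at 7085348 to 7125842 and measured 3.45 ± 1.53 RPKM in lean and 9.84 ± 6.07 RPKM in obese myotubes. The log2 fold change was 1.22 (SE 0.46, 95% interval 0.17 to 2.26), with all 3 obese values above the 3 lean values. The gene was among those with an unadjusted limma p under 0.05 and did not pass after adjustment over all genes (limma adjusted p = 1). The 2-sided exact permutation test gave p = 0.1, the smallest that 3 against 3 can give. Obese replicate 3 held the highest value, and without it the log2 fold change was 0.79. The unadjusted p was above 0.05 there, without lean replicate 1 (0.89 on the log2 scale) and after rescaling to equal sums (1.09), among other alternatives. With libraries weighted by their estimated quality the log2 fold change was 0.55 (limma unadjusted p = 0.0207, adjusted p = 0.0705). The 11 tested genes of the lysophospholipid remodelling list, to which LPCAT3 belongs, did not differ as a group (adjusted p = 0.324, camera), with a median of 0.13 relative to all genes. Of these, 0 genes passed over all genes tested and 0 when adjusted over the list alone. LCLAT1, a lysocardiolipin acyltransferase, measured 27.2 ± 21.1 and 44.9 ± 5.51 RPKM and LPCAT4 9.23 ± 2.41 and 13.6 ± 4.13 RPKM.

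Cell proliferation genes were higher in obese myotubes by the camera test with the preset correlation (33 genes, median 0.42 relative to all genes, adjusted p = 1.09e-06). The call was lost with an estimated correlation (adjusted p = 0.527), in fry (adjusted p = 0.442) and without lean replicate 3 (median 0.37, adjusted p = 0.0847), and the list median was 0.96 without obese replicate 1 and 0.67 without lean replicate 2. Of the 33 genes, 25 lay above the median of all genes, 9 had an unadjusted limma p under 0.05, and 0 passed over the list alone or over all genes. NUSAP1, a spindle protein, measured 13.7 ± 3.67 RPKM in lean and 33.7 ± 11.6 RPKM in obese myotubes, KIF20A, a kinesin of cytokinesis, 6.01 ± 4.23 and 20.5 ± 10.1 RPKM, and DLGAP5, a spindle assembly protein, 3.94 ± 2.81 and 12 ± 3.59 RPKM. The 24 tested myogenic regulators and fusion genes did not differ as a list (adjusted p = 0.943), with a median of 0.18 relative to all genes. Among them, ID2 and ID3, inhibitors of the myogenic factors, had log2 fold changes of -1.18 and -1.13 (-0.10 for ID2 with weighted libraries, -0.69 for ID3 without lean replicate 1), and MCAM, a cell adhesion molecule, one of 0.84. None of these passed after adjustment.

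Inflammation genes were lower in obese myotubes (17 tested NF-kB targets and cytokines, median -0.29 relative to all genes, camera adjusted p = 5.2e-06). The list also passed with an estimated correlation (adjusted p = 0.0469), but not in fry (adjusted p = 0.47), without a filter (median -0.04, adjusted p = 0.102) or without lean replicate 1 (median -0.35, adjusted p = 0.0902), and the list median was -0.50 without lean replicate 3 and -0.49 without obese replicate 1. Its mean log2 fold change was -0.26 and 4 of the 17 genes lay above the median of all genes. SAA1, an acute-phase protein, measured 117 ± 74.6 RPKM in lean and 35.2 ± 15.8 RPKM in obese myotubes. IL6 measured 3.12 ± 2.02 and 0.923 ± 0.276 RPKM and the chemokine IL8 38.3 ± 16.2 and 17.2 ± 17.3 RPKM. All 3 had an unadjusted limma p under 0.05, and 0 genes of the list passed over all genes or over the list alone. Interferon response genes did not pass (27 genes, adjusted p = 0.0923), and the test placed them lower although their median was 0.02 above that of all genes. They passed as lower without lean replicate 1 (adjusted p = 0.0286) or without obese replicate 3 (adjusted p = 0.00871). In this list IFI27 had a log2 fold change of -1.70, OAS1 one of -0.78 and GBP2 one of 0.65, and these were -0.13 for IFI27 with weighted libraries and 0.34 for GBP2 without lean replicate 1.

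The extracellular matrix list (44 genes, median -0.23 relative to all genes, camera adjusted p = 2.95e-05) and the list of oxidative stress genes, NRF2 targets and metallothioneins (26 genes, -0.25, adjusted p = 0.000297) were lower in obese myotubes relative to all genes. Their own medians were near 0, at -0.05 and -0.07, and 21 of 44 and 9 of 26 members had positive log2 fold changes. By library, the mean relative to all genes was highest in obese replicate 3 for the matrix list (0.35) and in lean replicate 1 for the oxidative stress list (0.58). Neither list passed with an estimated correlation (adjusted p = 0.557 and 0.483) or in fry (adjusted p = 0.912 for both). The matrix list did not pass without lean replicate 1 (adjusted p = 0.0895) or obese replicate 2 (median -0.06, adjusted p = 0.177), and its median was -0.39 without obese replicate 3 and -0.02 without a filter. The oxidative stress list did not pass without lean replicate 1, where its median turned to 0.07 (adjusted p = 0.838), or without obese replicate 1 (median -0.24, adjusted p = 0.0624), and its median was -0.41 without obese replicate 3. In limma 0 genes of either list had an unadjusted p under 0.05. TIMP3, an inhibitor of matrix metalloproteinases, measured 25.7 ± 15.5 RPKM in lean and 11.2 ± 4.03 RPKM in obese myotubes, COL12A1 2.43 ± 1.49 and 0.927 ± 0.237 RPKM, and LOXL1, which crosslinks elastin, 2.24 ± 1.29 and 1.08 ± 0.213 RPKM. GPX3, a secreted glutathione peroxidase, measured 11.2 ± 5.49 and 5.86 ± 1.77 RPKM and the metallothionein MT2A 1080 ± 701 and 573 ± 242 RPKM. GPX4, of the same list, went the other way over all libraries, with 70.2 ± 43.3 and 104 ± 16.3 RPKM (log2 fold change 0.84). That direction was not stable, with -0.01 without lean replicate 1 and obese replicate 3. It was -0.42 with a trend on gene length and GC removed and lean replicate 1 left out.

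The direction of cytosolic ribosomal protein genes depended on which libraries were included. Over all libraries the 70 genes were lower relative to all genes (median -0.15, own median 0.03, adjusted p = 0.00794), without passing under an estimated correlation (adjusted p = 0.914). Without lean replicate 1 they were higher (median 0.36 relative to all genes, adjusted p = 2.94e-10), and without obese replicate 3 the direction was also higher (median 0.10, adjusted p = 0.234). The median was -0.41 without lean replicate 2, -0.44 without lean replicate 3, -0.24 without obese replicate 1 and -0.32 without obese replicate 2. RPS15, RPL4 and RPL3 had log2 fold changes of 0.48, 0.42 and 0.42. The 79 nuclear-encoded genes of oxidative phosphorylation did not pass over all libraries (median -0.07 relative to all genes, own mean 0.19, adjusted p = 0.758), and without lean replicate 1 they were higher (median 0.27, adjusted p = 1.74e-08). They were lower without lean replicate 2 (adjusted p = 0.0306) or lean replicate 3 (adjusted p = 0.00017), and the direction was higher without obese replicate 3 (adjusted p = 0.58). COX6A2, the muscle form of a complex IV subunit, measured 70.8 ± 30 RPKM in lean and 156 ± 64.3 RPKM in obese myotubes, and NDUFB11 and NDUFS7 of complex I had log2 fold changes of 0.69 and 1.10. The 38 genes of the unfolded protein and integrated stress response were lower relative to all genes (median -0.15, own median 0.03, adjusted p = 0.0375), without passing under an estimated correlation (adjusted p = 0.837). They did not pass without lean replicate 1, 2 or 3 (medians -0.20, -0.16 and -0.10, adjusted p = 0.252, 0.062 and 0.0716) or without obese replicate 1 or 2 (medians -0.03 and -0.07, adjusted p = 0.603 and 0.278), and their median was -0.30 without obese replicate 3. PSPH, an enzyme of serine synthesis, PDIA3 and STC2 had log2 fold changes of 0.85, 0.62 and -0.47.

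Lists of fuel and membrane lipid metabolism did not pass the camera test. Glycolysis and glycogen genes had an adjusted p of 0.0867 (26 genes, median 0.13 relative to all genes), and ENO3, the muscle enolase, measured 527 ± 205 RPKM in lean and 1190 ± 351 RPKM in obese myotubes. PYGL and ALDOC of that list had log2 fold changes of 0.81 and 0.66, and the list passed as higher without obese replicate 2 (adjusted p = 0.00984), without a filter (adjusted p = 0.00668) and after quantile normalization (adjusted p = 0.0212). Of the 26 genes 24 had positive log2 fold changes. ALDOA went the other way, with 452 ± 493 RPKM in lean and 140 ± 243 RPKM in obese myotubes (log2 fold change -3.23, SE 2.84). Its SD exceeded its mean in both groups. Fatty acid uptake and oxidation genes had an adjusted p of 0.0923 (24 genes, median 0.15), with UCP2, a mitochondrial carrier, at 193 ± 104 and 350 ± 82.3 RPKM and log2 fold changes of 0.60 for ECHS1 and 0.52 for HADH. Phospholipid synthesis genes also had 0.0923 (18 genes, median 0.16), with log2 fold changes of 0.81 for LPIN3, 0.35 for AGPAT4 and 0.68 for AGPAT5. SREBP targets of sterol and fatty acid synthesis had 0.105 (25 genes, median 0.22), with 0.61 for FDPS, 0.56 for LSS and 0.55 for FADS1. They passed as higher without obese replicate 1 (adjusted p = 0.00935) or 2 (adjusted p = 0.00984) and turned lower without obese replicate 3 (adjusted p = 0.409). Sphingolipid genes (15 genes, adjusted p = 0.715, median -0.04, own median 0.14) included SGPL1 at 0.79, UGCG at -0.34 and DEGS1 at 0.36. SGPL1 and DEGS1 were both at -0.02 without lean replicate 1. Triglyceride storage genes (10 genes, adjusted p = 0.758, median 0.03) included FITM1, the 1 member that passed when adjusted over the list alone, PLIN3 at 1.01 and PLIN2 at 0.66. Insulin signalling and glucose uptake genes (29 genes, adjusted p = 0.758, median -0.03, own median 0.15) included GYS1, muscle glycogen synthase, at 5.32 ± 0.283 and 7.39 ± 0.259 RPKM, TBC1D1 at 0.32 and FOXO3 at 0.38.

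Among the remaining lists, caveolae and membrane microdomain genes had an adjusted p of 0.778 (15 genes, median 0.03), hypoxia targets one of 0.0764 (18 genes, median -0.12) and HOX and positional identity genes one of 0.88 (10 genes, median 0.04, although the test placed them lower). Hypoxia targets passed as lower without obese replicate 3 (adjusted p = 0.0309). The muscle caveolae genes CAV3 and MURC measured 55.5 ± 10.9 and 35.7 ± 12.6 RPKM in lean and 92.3 ± 24.9 and 66.7 ± 17.8 RPKM in obese myotubes, and ANXA6, a membrane-binding annexin, had a log2 fold change of 1.24. EGLN3 and LOX of the hypoxia list had 0.79 and -0.82. TBX15 and HOXC9, transcription factors of positional identity, had 0.94 and -0.54. None of these genes passed after adjustment.

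Of the 6 lists of markers of other cell types, the fibroblast list had enough members to be tested. The 10 tested fibroblast markers did not pass (camera adjusted p = 0.243), with a median of -0.28 relative to all genes (own median -0.10, own mean 0.10). They passed as lower without obese replicate 3 (median -0.39, adjusted p = 0.037), and the median was -0.05 without lean replicate 3. DCN, a proteoglycan of fibroblasts, measured 96.3 ± 52.5 RPKM in lean and 96.6 ± 42.9 RPKM in obese myotubes, and LUM 175 ± 78.4 and 117 ± 40.5 RPKM. THY1 measured 44.7 ± 14.8 and 79.7 ± 39.5 RPKM and CD34 1.24 ± 0.575 and 3.09 ± 0.55 RPKM, with non-overlapping groups in CD34. The other marker lists had fewer than 5 tested members and were not tested. Of 15 endothelial markers 0 reached a mean of 1 RPKM, the highest being CLDN5 at 0.404. Of 16 adipocyte markers 2 did, CD36 at 7.59 ± 6.86 and 12.8 ± 6.93 RPKM and ADIPOR2 at 2.22 ± 1.06 and 2.58 ± 0.384 RPKM. Of 16 leukocyte and macrophage markers 3 did, with CD68 at 50.8 ± 14.8 and 54.9 ± 23.4 RPKM, LYZ at 1.06 ± 0.385 and 1.12 ± 0.194 RPKM and FCER1G at 5.81 ± 5.85 and 3.60 ± 2.64 RPKM. Of 14 pericyte and smooth muscle markers 4 did, among them ACTA2, also expressed by differentiating myoblasts, at 2100 ± 727 and 3840 ± 939 RPKM (log2 fold change 0.90, non-overlapping groups), NOTCH3 at 3.58 ± 2.43 and 3.42 ± 0.29 RPKM and DES, a muscle intermediate filament gene, at 17.9 ± 3.16 and 25.6 ± 4.09 RPKM. Of 10 neural markers 2 did, TUBB3 at 3.57 ± 0.792 and 5.57 ± 3.88 RPKM and NGFR at 6.16 ± 1.38 and 7.30 ± 3.45 RPKM.

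Across all genes, limma called 0 of 8164 genes at an adjusted p under 0.05, the smallest adjusted p being 0.707. At an unadjusted p under 0.05 there were 208 genes, 188 higher and 20 lower in obese myotubes, where 408 would be expected by chance. The number was 562 without lean replicate 1 and 102 without obese replicate 2. The share of higher genes among the 208 was 90.4%, and it was 75.7% after rescaling to equal sums, 68.3% after median-of-ratios scaling and 66.7% after quantile normalization. It was 60.1% without lean replicate 1 (338 higher, 224 lower), 54.1% with a trend on gene length and GC removed, and 40.3% (234 higher, 346 lower) with both. Groups did not overlap in 688 genes (8.43%, where chance gives 10%), 653 of them higher in obese myotubes. Weighting the libraries by their estimated quality gave 1879 genes (1432 higher, 447 lower), with a weight of 0.13 for lean replicate 1 and 7.71 for obese replicate 2. Leaving out lean replicate 1 and obese replicate 3 gave 106 genes (59 higher, 47 lower). These libraries were picked after seeing that they lay farthest from the others. Such a choice tends by itself to narrow the spread within groups and to favour calls.

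Lean replicate 1 stood apart from the other libraries. Its mean Pearson correlation with them, across genes, was 0.905, against 0.936 to 0.959 for the others, and it lay at -70.9 on the first principal component, which held 53.9% of the variance. Obese replicate 3 lay at 47.3 on the second component (24.2%). Longer genes had lower values in lean replicate 1 than in the other libraries (Spearman correlation across genes -0.36 of exonic length with the centred log2 value), while the correlation was 0.34 and 0.37 in lean replicates 2 and 3 and 0.26, -0.23 and -0.07 in obese replicates 1 to 3. For GC content the correlation was 0.41, -0.35 and -0.5 in lean replicates 1 to 3 and -0.47, 0.04 and 0.37 in obese replicates 1 to 3. Obese replicate 3 thus had nearly the same GC trend as lean replicate 1. The 10 most abundant genes held 18.7% of the summed RPKM in lean replicate 1 and 13.3 to 14.7% in the others. The 41 sarcomere genes had a median exonic length of 3183 bp, against 5264 bp for all tested genes. Without lean replicate 1 the sarcomere list median was 0.82 relative to all genes, and after a trend on gene length and GC content had been removed from each library it was 0.90.

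**Figure D3:**
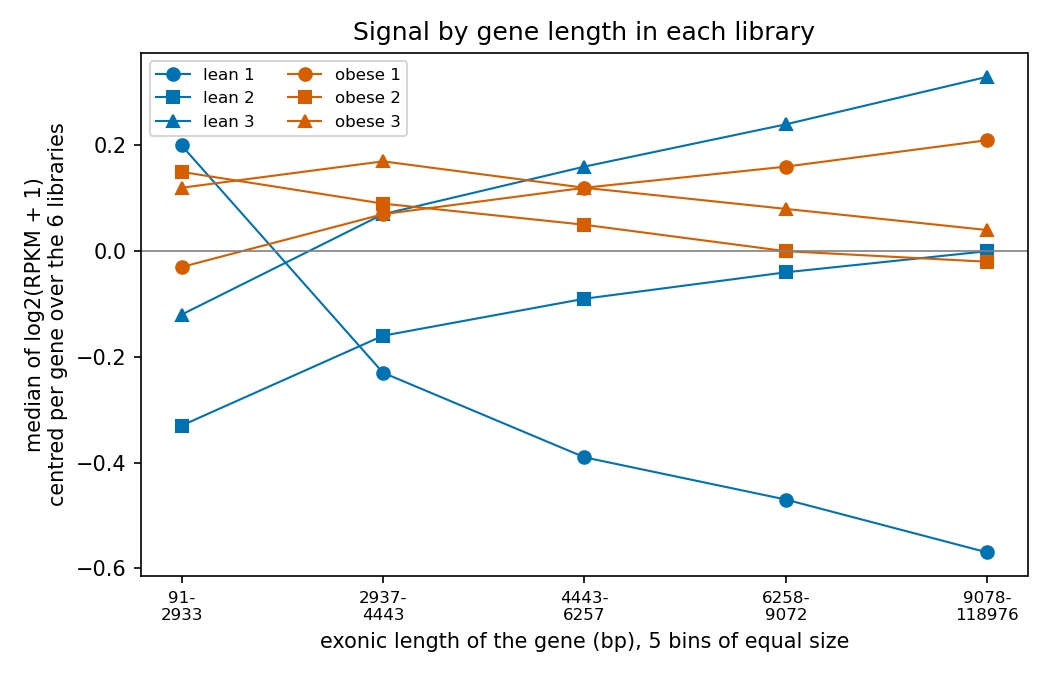
Median of log2(RPKM + 1), centred per gene over the 6 libraries, for tested genes in 5 bins of exonic length (bp) in each library, with lean libraries in blue and obese in orange. In lean replicate 1 the median goes from 0.20 in the shortest to -0.57 in the longest genes, and in lean replicate 3 from -0.12 to 0.33.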

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

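The result was recomputed under 24 alternatives, of which the 4 that remove a length and GC trend, use genes of known length and GC alone, or leave out lean replicate 1 with obese replicate 3 or with the trend were chosen after seeing the data. The sarcomere and excitation-contraction lists stayed higher and past the threshold in all 24, with adjusted p from 3.26e-44 to 0.0469 and from 1.09e-20 to 0.0469. All but the 2 further list tests used camera at the preset correlation, which called 3 to 7 lists in other splits of the libraries. These refits are therefore not separate support. The exact permutation test of the mean score of either list gave p = 0.1, the smallest possible. The medians of the 2 lists relative to all genes, 0.88 and 0.68 as reported, were 0.56 and 0.45 under arrayWeights. They were 0.73 and 0.39 with the trend removed and lean replicate 1 left out. LPCAT3 stayed higher and short of the threshold in all refits, with log2 fold changes from 0.46 without lean replicate 1 and obese replicate 3 to 1.47 without obese replicate 1. For 83 named genes, 1723 of 1794 values kept direction and side of the threshold, 60 passed it, 46 of them under arrayWeights, and 11 changed sign in 5 genes. The log2 fold change of 45 of the 83 moved by over 1.5 times when some library was left out, of 22 without lean replicate 1 and of 33 under arrayWeights. IFI27 went from -1.70 to -0.13 and ID2 from -1.18 to -0.10 under arrayWeights. Of 192 values of the 8 called lists, 152 kept call and direction, 33 lost the call and 7 changed direction, and of 359 values of the other lists 301 kept both. Where no reason is given below, the cause was not tested.

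Genes past the threshold numbered 0 in every refit except 2. Library weights (arrayWeights) gave 1879, of which 1432 were higher and 447 lower, with 3255 at an unadjusted p under 0.05, and the fit rested on few libraries, with weights of 0.13 for lean replicate 1 and 7.71 for obese replicate 2. Leaving out lean replicate 1 and obese replicate 3 gave 106, with 59 higher and 47 lower, and 1105 at an unadjusted p under 0.05. The latter count was 627 without a filter, where more genes were tested, 98 at a mean RPKM of at least 5, where fewer were, 115 after rescaling to equal sums, 580 with the trend removed and lean replicate 1 left out, and 102 (without obese replicate 2) to 562 (without lean replicate 1) with each library left out in turn. The share of higher genes among those was 90.4% as reported, 60.1% without lean replicate 1, 54.1% with the trend removed and 40.3% (234 higher, 346 lower) with both.

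Sarcomere genes that passed over the list alone numbered 0 after rescaling to equal sums, median-of-ratios scaling or quantile normalization, 5 with the trend removed, 0 when lean replicate 1 was left out as well, and 0 to 25 with each library left out, 0 without lean replicate 3 or obese replicate 2 and 6 without obese replicate 3. The corresponding excitation-contraction counts were 2, 3, 1, 1 and 2, and 1 to 7 with each library left out, 1 without lean replicate 3 or obese replicate 1 and 3 without obese replicate 2. They were 2 at a mean RPKM of at least 5, 15 under arrayWeights and 10 without lean replicate 1 and obese replicate 3.

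The number of lists past the threshold was 4 without a filter, 3 with an estimated correlation and 2 in fry, which compares a list with no other genes. The proliferation list had adjusted p of 0.527 with an estimated correlation, 0.442 in fry and 6.04e-14 to 0.0847 with each library left out, the call ending without lean replicate 3. Inflammation genes had 0.47 in fry, 0.102 without a filter and 1.15e-08 to 0.0902 with each library left out, the call ending without lean replicate 1. The matrix list had 0.557 with an estimated correlation, 0.912 in fry, 0.102 without a filter and 1.56e-10 to 0.177 with each library left out, ending without lean replicate 1 (0.0895) or obese replicate 2 (0.177). Oxidative stress genes had 0.483, 0.912, 0.102 and 7.18e-06 to 0.838 in the same order, ending without lean replicate 1 (0.838, list median 0.07) or obese replicate 1 (0.0624), 0.875 under arrayWeights (list median 0.01) and 0.548 without lean replicate 1 and obese replicate 3. The stress response list had 0.837 with an estimated correlation, 0.912 in fry with the direction turned, 0.431 without a filter, 0.101 at a mean RPKM of at least 5, 0.0711 after rescaling to equal sums, 0.0929 under arrayWeights and 4.67e-05 to 0.603 with each library left out, where it kept the call in 1 of the 6 omissions, that of obese replicate 3. Lysophospholipid remodelling passed only at a mean RPKM of at least 5 (adjusted p = 0.0452), where fewer of its genes were tested.

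Ribosomal protein genes lost the call without a filter (adjusted p = 0.487), after quantile normalization (0.325), with the trend removed (0.098) and with an estimated correlation (0.914). They turned higher under arrayWeights (adjusted p = 2.21e-14), without lean replicate 1 and obese replicate 3 (4.64e-28), with the trend removed and lean replicate 1 left out (5.14e-06) and in fry (0.924), and ranged from 1.69e-13 to 0.234 with each library left out, turning higher without lean replicate 1 (2.94e-10) or obese replicate 3 (0.234). Oxidative phosphorylation genes turned higher under the first 3 of these (adjusted p = 7.47e-08, 9.33e-10 and 2.65e-05), in fry (0.776), without a filter (0.367), after quantile normalization (0.62) and with the trend removed (0.752), and ranged from 1.74e-08 to 0.992 with each library left out, turning higher without lean replicate 1 (1.74e-08) or obese replicate 3 (0.58) and passing as lower without lean replicate 2 (0.0306) or 3 (0.00017).

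SREBP targets passed as higher without obese replicate 1 (adjusted p = 0.00935) or 2 (0.00984) and glycolysis genes without obese replicate 2 (0.00984), without a filter (0.00668) and after quantile normalization (0.0212). Hypoxia targets passed as lower without obese replicate 3 (adjusted p = 0.0309) and without it and lean replicate 1 (0.0247), and fibroblast markers without obese replicate 3 (0.037). Interferon genes passed as lower without obese replicate 3 (adjusted p = 0.00871), lean replicate 1 (0.0286) or both (0.00104), and with the trend removed and lean replicate 1 left out (0.0246). Other uncalled lists that changed direction did so under arrayWeights (glycolysis, adjusted p = 0.875; SREBP targets, 0.575; triglyceride storage, 0.976; HOX genes, 0.465), without lean replicate 1 and obese replicate 3 (SREBP targets 0.123, triglyceride storage 0.783, HOX genes 0.765), without a filter (sphingolipid genes 0.974, insulin signalling 0.367), at a mean RPKM of at least 5 (myogenic regulators 0.0633) and with the trend removed and lean replicate 1 left out (caveolae 0.971, myogenic regulators 0.912). In fry the direction turned for hypoxia targets, interferon genes and fibroblast markers (adjusted p = 0.912 each), sphingolipid genes (0.777), insulin signalling (0.567) and HOX genes (0.567). With each library left out in turn, adjusted p ranged from 0.00935 to 0.787 for SREBP targets, 0.00871 to 0.814 for interferon genes, 0.037 to 0.942 for fibroblast markers, 0.253 to 0.998 for sphingolipid genes, 0.163 to 0.921 for triglyceride storage, 0.5 to 0.998 for insulin signalling, 0.402 to 0.921 for caveolae, 0.385 to 0.743 for HOX genes and 0.248 to 0.921 for myogenic regulators.

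Single genes that changed sign were AGPAT5 (log2 fold change -0.03), SGPL1 (-0.25) and DEGS1 (-0.32) under arrayWeights, SGPL1 (-0.24), DEGS1 (-0.27), GPX4 (-0.01) and STC2 (just above 0, 0.00) without lean replicate 1 and obese replicate 3, and DEGS1 (-0.13) and GPX4 (-0.42) with the trend removed and lean replicate 1 left out. With each library left out, SGPL1 ranged from -0.02 to 1.32 and DEGS1 from -0.02 to 0.58. The replicate block, run because both groups use the numbers 1 to 3, gave 0 genes, with 173 at an unadjusted p under 0.05. It ended the call of the stress response list (adjusted p = 0.0741), brought SREBP targets past the threshold (adjusted p = 0.0428) and changed no other call of a list or gene. No label says that the numbers pair the samples. Deviations of same-numbered samples correlated at -0.34, -0.36 and -0.22 across genes, against up to 0.45 for samples of different number. Such deviations also carry the length and GC trends of the libraries, so the correlations cannot settle whether the numbers stand for a shared batch. Depth, 20.9 to 25.6 M reads per library, limits genes under the minimum of 1 RPKM, tested only without a filter, more than those tested. With the spread within groups of these libraries, 15.2% of simulated changes of 1 on the log2 scale were recovered, 81.2% of those of 2 and 97.2% of those of 3. The simulated genes varied independently, and 50 were changed at each size, which makes the adjustment more lenient. These shares can therefore overstate the recovery in the real libraries.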

Other observations

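The gene sets of the first 2 paragraphs and, further down, the tests of fibroblast admixture and depth in lean replicate 1, of lean replicate 1, the trend removal, fibroblasts and cycling myoblasts for the sarcomere genes, and of obese replicate 3 for LPCAT3 were chosen only after the result was seen. Troponin genes of fast fibres had larger fold changes than those of slow fibres. The mean log2 fold change of TNNC2, TNNT3 and TNNI2, the fast forms, was 0.74 above that of TNNC1, TNNT1 and TNNI1, the slow forms. The fast-minus-slow difference was -1.24 ± 0.33 (SD, n = 3) in lean and -0.49 ± 0.48 in obese libraries, without overlap, and was given no test because the genes were picked for it. TNNI2 measured 10.6 ± 5.57 RPKM in lean and 31 ± 14.6 RPKM in obese myotubes, and TNNI1 185 ± 57.8 and 334 ± 47.6 RPKM. The difference was 0.47 without obese replicate 3 and 0.44 without lean replicate 1 and obese replicate 3. Other fast and slow forms did not part this way, so the difference holds for the troponins alone. The fast MYBPC2 had a log2 fold change of 0.81 against 1.73 for the slow MYBPC1, and the fast MYLPF 1.05 against 1.25 for the slow MYL2. Of the fast myosin heavy chains, MYH2 had 0.78 and MYH1 0.34, against 0.58 for the slow MYH7.

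Within the proliferation list, genes of mitosis and genes of DNA replication parted. CCNA2, a cyclin of both phases, was placed in neither set (log2 fold change 0.04, or -0.14 relative to all genes). The 21 genes taken as mitotic all lay above the median of all genes, with a median of 0.76 relative to it, among them CCNB1, the mitotic cyclin B1 (32 ± 5.95 RPKM in lean and 87.7 ± 47.3 RPKM in obese myotubes), and the kinase AURKA (8.25 ± 2.58 and 18.8 ± 7.44 RPKM). Of 11 replication genes 4 did, with a median of -0.11, and PCNA, the sliding clamp of DNA polymerase, measured 73.1 ± 39.3 and 57 ± 9.69 RPKM. The mitosis-minus-replication difference was -0.11 ± 0.69 in lean and 0.70 ± 0.26 in obese libraries (0.81 higher), and 0.42 higher without lean replicate 1. The ID genes, inhibitors of the myogenic factors, averaged 1.45 ± 0.82 above the median of all genes in lean and 0.26 ± 0.24 in obese libraries over ID2, ID3 and ID4. ID1 was not among the tested genes. The 3 were picked for being lower, by -1.19 as a mean and by -0.74 without lean replicate 1, so this restates their single values.

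Lean replicate 1 stood apart in its mean correlation with the other libraries (0.905, against 0.936 for the next lowest). Removing a trend on gene length and GC narrowed the gap from 0.0305 to 0.0238 and took away 22.8% of the variance of its deviations. The gap stayed above the 0.02 set beforehand, so the trend as fitted did not account for all of it. The SE of the gap, 0.00143 over 100 resamplings of genes, does not cover differences between libraries. Lengths came from GENCODE and not from the RefSeq gene model, so a leftover of the trend stays open. The depth of lean replicate 1 was 99.1% of that of the next library, which argues against depth. Fibroblast markers lay a median of 0.30 above the other 5 libraries relative to all genes (SE of the mean 0.26 over 10 markers, 4 of them lower), and admixture stays open because the markers scatter this widely. Differences between donors and an unrecorded batch also stay open and were not tested.

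Sarcomere genes were higher in obese myotubes, with a list median of 0.88 relative to all genes, against 0.57 in the highest other split (the real split alone, 1 of 10, gave as much, and 10 splits are too few for a share under 0.05). The median was 0.82 without lean replicate 1 and 0.90 with the length and GC trend removed, which argues against that library alone and against the trend. The argument rests on these medians. In camera at the preset correlation the adjusted p were 1.94e-20 and 7.57e-35, but other splits of the libraries also brought lists past that test. Over all alternatives the adjusted p ranged from 3.26e-44 to 0.0469. More cycling myoblasts in the lean cultures, if such cells made up 50% of the obese cultures or less, would need proliferation genes at -0.55 or lower, and these had a median of 0.42 (SE of the mean over genes 0.09) and a mean of 0.44 (SE 0.35 between libraries), which argues against them at those shares. Fibroblast markers, held to the same -0.55, had a mean of -0.12 (SE 0.17 between libraries) and a median of -0.28 (SE of the mean 0.16 over 10 markers that go both ways), -0.39 without obese replicate 3 and -0.05 without lean replicate 3, so more fibroblasts in the lean cultures stay open. Also open are unfused myoblasts out of cycle, which have no list here, culture timing and, as an untested hypothesis, a difference in differentiation that goes with donor obesity.

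For the counts, too, 10 splits are too few for a share under 0.05. The real split gave 8 lists past the threshold, the highest of the others 7, and 1 of 10 splits gave as many. Genes with an adjusted p under 0.05 in limma numbered 0 in the real split and at most 9 in the others, and since every split reaches 0, the 10 of 10 that gave as many say nothing about chance. At an unadjusted p under 0.05 the real split gave 208 genes, 5 of 10 splits gave as many, and the split of lean replicate 1, obese replicate 2 and obese replicate 3 against the others gave 1313. That is several times the real count and points to a structure of the samples other than the donor groups. The same split parts the libraries by their GC and length trends. Spearman correlations with GC were 0.41, 0.04 and 0.37 in lean replicate 1 and obese replicates 2 and 3. In lean replicates 2 and 3 and obese replicate 1 they were -0.35, -0.5 and -0.47. Those with exonic length were -0.36, -0.23 and -0.07 against 0.34, 0.37 and 0.26. Whether these trends account for the count was not tested.

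LPCAT3 had a log2 fold change of 1.22 and non-overlapping groups. Without obese replicate 3 the log2 fold change was 0.79 (limma unadjusted p = 0.0982), above the bound of 0.61. It was 0.55 under arrayWeights and 0.46 with lean replicate 1 left out as well, both below the bound. Obese replicate 3 as the main source therefore stays open. Reads of an overlapping gene are argued against, as 0 tested genes overlap its coordinates with a fold change as large. Of 17 other targets of the sterol sensor LXR, which also controls LPCAT3, 8 were tested. Their median was 0.12 relative to all genes (SE of the mean over genes 0.10), against 1.03 for LPCAT3, with 0.47 for SCD. ABCA1 measured 0.875 RPKM in lean and 1.88 RPKM in obese myotubes, and PLTP 2.31 and 4.71 RPKM. The log2(RPKM + 1) scale shrinks such weak genes, here to 0.38 and 0.35. APOE went the other way, with 1.26 and 0.847 RPKM. As a set the targets rose less than LPCAT3, but the SE does not cover donors and several targets are weakly expressed. An LXR response therefore stays open. Chance among 3 donors a group (exact permutation p = 0.1) and donor obesity, as an untested hypothesis, stay open.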
